A study of Homo sapiens with 6 samples.

How the data were processed

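The samples were 6 libraries of HCT116, an established human colorectal cancer cell line, 3 from cells given 50 nM TR-107 and 3 from cells given the vehicle, 0.1% DMSO, for 24 h. Per the labels' protocols, total RNA was purified on columns, mRNA was enriched by its poly(A) tail and the libraries were read as pairs on an Illumina instrument. The deposited values were raw read counts per gene, which the authors made with featureCounts, per the submitters' processing notes. The same notes name FastQC, Trimmomatic, the aligner HISAT2 and the genome build hg38. Their versions, the gene annotation, and the strand and multi-mapping settings of the counting are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical copies may therefore be split or lost in ways that the counts do not show.

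Each file held whole-number counts for 28395 gene IDs, which were used as deposited. Of these, 27745 matched a symbol in an NCBI RefSeq gene table of GRCh38.p14, the same assembly as hg38, and 650 did not. Unmatched IDs held 0.0390% to 0.0502% of a library's counts and stayed, under their ID, in the counts that were scaled, filtered and tested. A count of 0 in all 6 libraries was found for 9091 genes. Total counts were 17264039 to 23708135 per library, and 16199 to 17069 genes per library had a count. Groups and replicate numbers came from the sample titles and treatment labels.

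The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with TMM scaling, the filter filterByExpr, a robust dispersion fit, a design with the group alone, and Benjamini-Hochberg adjustment at 0.05. CPM values were computed from TMM-scaled library sizes, and fold changes are TR-107 over DMSO, with a prior count of 2 in the log2 CPM used for gene lists. A second count took genes past that threshold with an absolute log2 fold change of at least 1. Gene lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 38 lists tested. Camera with a correlation estimated per list, and fry, stand beside it. Fry asks whether the genes of a list move on balance in 1 direction, and its mixed form whether they change in either direction, without comparison to other genes. The share of counts from mitochondrially encoded genes was compared by an exact two-sided permutation test, for which 3 libraries against 3 allow no p below 0.1.

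The design, the named genes, 41 gene lists and most alternatives were chosen before the data were examined. Genes are named by 3 rules. The first takes the 12 highest and the 12 lowest fold changes among called genes with a mean of at least 5 CPM whose groups do not overlap. The second takes 20 genes fixed by name whatever their values. The third takes, from each list, up to 4 members per direction with the smallest p. The mitochondrial rRNA genes, the untested or uncalled members of lists with fewer than 5 tested genes, and the genes of the closing section's added lists were chosen outside these rules, after the main results were seen. Some genes that the rules name are not reported here. Of the 257 genes named by rule or in their tables, 82 overlap another annotated gene, and 17 genes stand in more than 1 fixed list. The alternatives were relative log expression and upper-quartile factors, library size without scaling, no filter on low counts, a minimum of 1 CPM in 3 libraries, the replicate number as a block, DESeq2 1.42.0, limma-voom, a test against 2-fold (glmTreat), and leaving out each library in turn. Leaving out the mitochondrial genes before scaling, and shares of the 13 mitochondrial protein-coding or 2 rRNA genes alone, were added after the data were seen. SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the shares and the plots.

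The tests were checked on simulated counts drawn from the real means and library sizes for TR-107 against DMSO, with 200 changed genes. The changed genes were drawn only from genes above a minimum mean count, so recovery among genes with low counts was not measured. Of the simulated changes of 1.5, 2 and 4-fold, 72%, 94% and 100% were called, and of a still smaller change 70%, in the right direction among 13444 genes, and 0.0982% of unchanged genes were called. Camera and fry each recovered 2 of 2 changed lists and called 0 of 30 unchanged ones. The simulated genes varied independently of each other and few were changed, unlike the real ones. This check therefore does not measure how often lists of correlated genes are called falsely. Replicate libraries were checked for duplicates by a chi-square statistic of their counts, which was 4 to 6.21 per degree of freedom within groups, so no pair lay within sampling noise and each library was counted as 1 replicate. The common biological coefficient of variation was 0.0739.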

Results

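TR-107 is a small-molecule agonist of ClpP, the proteolytic subunit of a protease complex of the mitochondrial matrix. To ask which genes and pathways change when this protease is activated in colorectal cancer cells, polyadenylated RNA of HCT116 cells was sequenced after 24 h in 50 nM TR-107 (3 libraries) or in 0.1% DMSO (3 libraries). The design text calls the libraries of a group biological replicates without saying how the cultures were separated, so the p-values measure the spread between these libraries. Libraries held 18344471, 22295528 and 23708135 gene counts in DMSO and 17264039, 18694722 and 22243758 in TR-107 (replicates 1, 2 and 3).

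After TR-107, all 22 tested genes of the integrated stress response were higher than in DMSO, and most tested genes of cholesterol synthesis, DNA replication and the mitochondrial ribosome were lower. Mitosis genes and 7 further nuclear-encoded mitochondrial lists also passed camera as lower, but lost the call with an estimated correlation (camera adjusted p = 0.118 with an estimated correlation for mitosis, and 0.0721 to 0.137 for the mitochondrial lists). DDIT4, an inhibitor of mTORC1 signalling, rose from 26.3 ± 1.92 CPM (SD, n = 3) to 568 ± 28.9 CPM (SD, n = 3), which was 21.6-fold. ASNS, asparagine synthetase, rose from 88.5 ± 3.12 to 836 ± 8.62 CPM (SD, n = 3), which was 9.45-fold. CYP24A1, which inactivates vitamin D, fell from 191 ± 5.57 to 18.8 ± 2.69 CPM (SD, n = 3) and was 10.1-fold lower. The 2 mitochondrial rRNAs rose by 2.92 (MT-RNR1) and 2.08 (MT-RNR2) on the log2 scale.

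Of 13767 genes tested, 7956 (57.8%) were called at a Benjamini-Hochberg adjusted p under 0.05 by edgeR's quasi-likelihood test, 4015 higher and 3941 lower. Among these, 902 were at least 2-fold higher and 511 at least 2-fold lower, and 4627 (58.2%) had changed by less than 1.5-fold. A test against 2-fold itself (glmTreat) called 545 genes, 385 higher and 160 lower. The 3 TR-107 libraries lay on 1 side of all 3 DMSO libraries for 8596 tested genes (62.4%), where chance gives 10%. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.9834 to 0.9894 within groups and 0.9537 to 0.9564 between them. The first principal component held 66.1% of the variance, with scores of -40.9 to -40.5 for DMSO and 39.7 to 41.5 for TR-107.

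**Figure D1:**
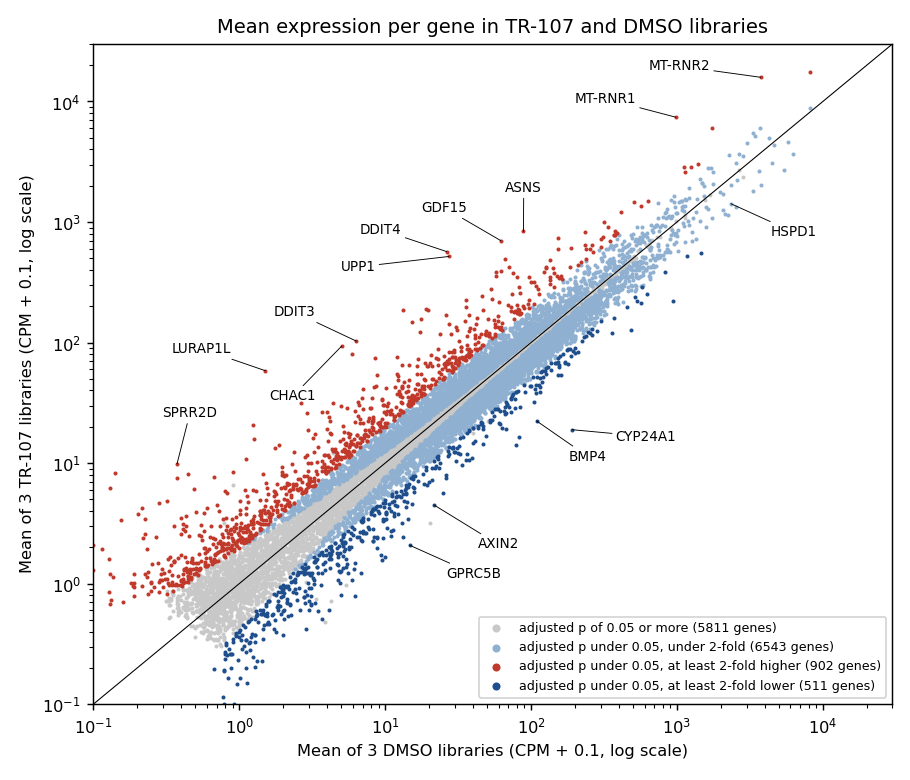
Mean TMM-scaled CPM of each tested gene in 3 DMSO libraries (x axis, log scale) and 3 TR-107 libraries (y axis, log scale), with 0.1 added to both, coloured by edgeR call; the line marks equal means. The 902 genes at least 2-fold higher lie above the line and the 511 at least 2-fold lower lie below it, with LURAP1L, DDIT4, CYP24A1 and the mitochondrial rRNAs among those labelled.

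The 12 genes with the highest fold changes were LURAP1L, SPRR2D, DDIT4, CHAC1, UPP1, IL20RB, DDIT3, SLFN5, NRP1, HKDC1, LAMP3 and GDF15, with log2 fold changes from 5.38 ± 0.14 (SE) for LURAP1L down to 3.50 ± 0.05 (SE) for GDF15. LURAP1L (gene ID 286343, GRCh38 chromosome 9, 12775020 to 12823060) rose from 1.41 ± 0.505 to 58.3 ± 2.47 CPM (SD, n = 3), with an adjusted p of 2.97e-30 by edgeR. UPP1 (gene ID 7378), a uridine phosphorylase, rose from 27.2 ± 2.26 to 518 ± 9.99 CPM (SD, n = 3). CHAC1, which degrades glutathione, rose 18.9-fold, and DDIT3, which encodes the transcription factor CHOP, rose 16.4-fold. GDF15 (gene ID 9518), a secreted stress cytokine, rose from 61.9 ± 3.32 to 701 ± 47.4 CPM (SD, n = 3). HKDC1, a hexokinase family member, had the widest error of the 12 (log2 fold change 3.77 ± 0.41, SE; edgeR adjusted p = 7.21e-05), and its fold rose from 13.7 to 24.6 without DMSO replicate 2. SPRR2D, from 0.274 to 9.73 CPM, moved from a log2 fold change of 5.19 to 5.78 without DMSO replicate 1.

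The 12 genes with the lowest fold changes included CYP24A1, GPRC5B, ITGB8, RASSF2, DACT1, LFNG, INSIG1, BMP4, AXIN2, RGMA and RAB3A, with log2 fold changes from -3.34 ± 0.07 (SE) for CYP24A1 to -2.20 ± 0.20 (SE) for RAB3A. CYP24A1 (gene ID 1591, GRCh38 chromosome 20, 54143538 to 54173986) had an edgeR adjusted p of 3.34e-33. BMP4, a secreted morphogen, fell from 109 ± 0.974 to 22.3 ± 0.741 CPM (SD, n = 3). LFNG, a modifier of Notch receptors, was 5.57-fold lower. The spans of LURAP1L, DDIT3, SLFN5, HKDC1, GDF15, GPRC5B, ITGB8, LFNG and RAB3A overlap another annotated gene (MARS1 in the case of DDIT3), and SPRR2D belongs to a family of closely similar copies, so their counts are less certain.

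All 22 tested members of the integrated stress response list, targets of ATF4 and CHOP, rose, with a median of 6.66-fold, and 21 of them rose at least 2-fold. ATF4 itself, the main transcription factor of the response, rose from 400 ± 8.19 to 777 ± 10.5 CPM (SD, n = 3). SESN2, a leucine sensor and mTORC1 inhibitor, rose 10.1-fold, and TRIB3, a pseudokinase that acts back on the response, rose 6.67-fold. STC2, a secreted glycoprotein, rose from 71 to 427 CPM. The list had a camera adjusted p of 5.98e-15, and adjusted p = 0.0161 with an estimated correlation.

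**Figure D2:**
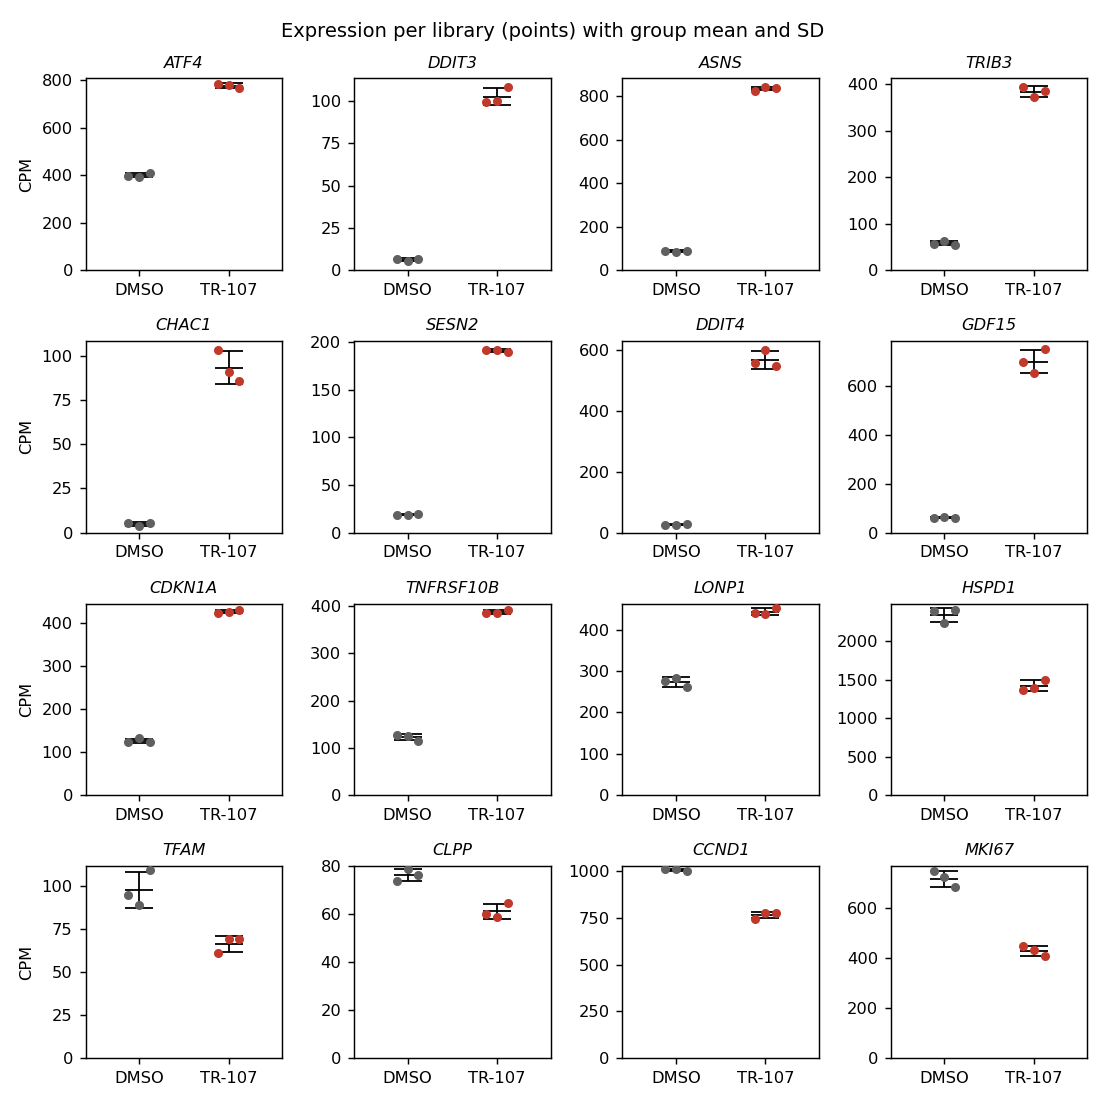
TMM-scaled CPM per library (points; 3 DMSO, 3 TR-107) for 16 of the genes fixed by name, each on its own axis from 0, with group mean and SD. All 3 TR-107 values lie above all 3 DMSO values for ATF4, DDIT3, ASNS, TRIB3, CHAC1, SESN2, DDIT4, GDF15, CDKN1A, TNFRSF10B and LONP1, and below them for HSPD1, TFAM, CLPP, CCND1 and MKI67.

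Of 11 tested amino acid transporters, 10 rose and 1 fell. SLC7A5, the light chain of the large neutral amino acid transporter, rose from 1387 to 3019 CPM, its partner SLC3A2 rose 2.12-fold, and SLC38A2, a carrier of small neutral amino acids, rose 2.40-fold, while SLC36A1, a lysosomal exporter, fell (log2 fold change -0.63 ± 0.13, SE). The list passed camera (adjusted p = 1e-05), with adjusted p = 0.0913 with an estimated correlation. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, 12 rose and 5 fell, with a camera adjusted p of 0.00547 and adjusted p = 0.136 with an estimated correlation. SARS1 (1.84), WARS1 (1.56), AARS1 (1.45) and GARS1 (1.31) rose on the log2 scale, and RARS1 (-0.59), FARSA (-0.61), KARS1 (-0.28) and HARS1 (-0.33) fell. Of 13 genes of serine, one-carbon and proline synthesis, 7 rose and 3 fell (8 and 3 adjusted over the list alone), with a camera adjusted p of 0.0292 and adjusted p = 0.139 with an estimated correlation. PHGDH (4.40-fold) and PSAT1 (3.23-fold), which act early in serine synthesis, and MTHFD2 (2.21-fold), a mitochondrial folate enzyme, rose, whereas the cytosolic folate enzymes SHMT1 (-0.67) and MTHFD1 (-0.30) fell on the log2 scale. Adjusted over the list alone, the counts of the other lists of this and the previous paragraphs were the same.

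CLPP, the target of TR-107, fell from 76.5 ± 2.53 to 61.3 ± 3.05 CPM (SD, n = 3), a log2 fold change of -0.32 ± 0.06 (SE; edgeR adjusted p = 2.76e-05). It lies on GRCh38 chromosome 19, 6361531 to 6370242 (gene ID 8192). CLPX, the unfoldase that feeds substrates to ClpP, did not pass the test (75.4 ± 3.84 and 73.0 ± 5.38 CPM, SD, n = 3; edgeR adjusted p = 0.545). LONP1, another matrix protease, whose span overlaps RPL36, rose 1.62-fold, and HSPD1, the mitochondrial chaperonin, was 1.65-fold lower (2342 ± 88.7 and 1419 ± 71.7 CPM, SD, n = 3). Among 22 mitochondrial chaperones and proteases, 4 rose and 12 fell (5 and 12 adjusted over the list alone), with HSPA9 (0.37), GRPEL2 (0.42) and YME1L1 (0.26) among those that rose and HSPE1 (-1.51), PHB1 (-0.69) and PMPCA (-0.77) among those that fell. This list missed the threshold (camera adjusted p = 0.0527; 0.162 with an estimated correlation). It passed without DMSO replicate 3 (camera adjusted p = 0.0418), TR-107 replicate 2 (0.0465) or TR-107 replicate 3 (0.049), and with no filter on low counts (0.0346), within a range of 0.0346 to 0.0813 over the settings with camera's preset correlation, and fry gave an adjusted p of 0.000107.

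Nuclear genes for mitochondrial ribosomes fell together: of 75 tested mitochondrial ribosomal proteins 61 fell and 4 rose (62 and 5 adjusted over the list alone), with a median log2 fold change of -0.32. MRPS34 fell from 159 to 76.5 CPM and MRPL12 from 260 to 160 CPM, while MRPS10 rose from 90.1 to 142 CPM. Camera gave this list an adjusted p of 2.72e-09, and adjusted p = 0.0170 with an estimated correlation. Of 26 factors of mitochondrial DNA maintenance, transcription and translation, 15 fell and 3 rose. TFAM, which packages mitochondrial DNA, fell from 97.4 ± 10.4 to 66.4 ± 4.70 CPM (SD, n = 3), TUFM, the mitochondrial elongation factor, was 1.23-fold lower, and POLRMT, the mitochondrial RNA polymerase, had a log2 fold change of -0.55 (camera adjusted p of the list 0.00324, and adjusted p = 0.137 with an estimated correlation). Of 16 mitochondrial aminoacyl-tRNA synthetases, 10 fell, LARS2 (-0.87) and EARS2 (-0.69) among them, and 2 rose, WARS2 (0.74) and RARS2 (0.28), with a camera adjusted p of 0.0102 and adjusted p = 0.0993 with an estimated correlation. Of 19 import components, 14 fell, including TOMM40 (-0.92) and TIMM13 (-0.79), and 4 rose, including TIMM17B (0.79), with a camera adjusted p of 0.00547 and adjusted p = 0.136 with an estimated correlation.

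Of 17 nuclear ATP synthase subunits, 15 fell and 1 rose, with ATP5MC3 down from 186 to 100.4 CPM (camera adjusted p = 0.000272, and adjusted p = 0.0721 with an estimated correlation). The 1 that rose, ATP5MC2 (log2 fold change 0.15), lost its call without DMSO replicate 2 or 3 or TR-107 replicate 2, and with library size alone. Of 25 subunits of complexes II to IV and cytochrome c, 17 fell and 0 rose, among them SDHA (-0.58), UQCRFS1 (-0.59) and CYCS (-0.44), with a camera adjusted p of 0.000766 and adjusted p = 0.0721 with an estimated correlation. Of 35 nuclear complex I subunits, 17 fell and 2 rose, with NDUFAB1 at -0.66 and NDUFS4 at 0.55 on the log2 scale (camera adjusted p = 0.00252, and adjusted p = 0.0771 with an estimated correlation). Of 22 genes of the cycle and pyruvate dehydrogenase, 15 fell and 4 rose (16 and 4 adjusted over the list alone), with DLAT (-0.64) and IDH3A (-0.60) lower (camera adjusted p = 0.00196, and adjusted p = 0.0913 with an estimated correlation). The medians of these lists lay between -0.33 and -0.15. Among the genes that rose, NDUFA13 of complex I and SUCLG2 and IDH2 of the cycle lost their calls under some alternatives. IDH2, for example, lost its call with the replicate number as a block (edgeR adjusted p = 0.0592).

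**Figure D3:**
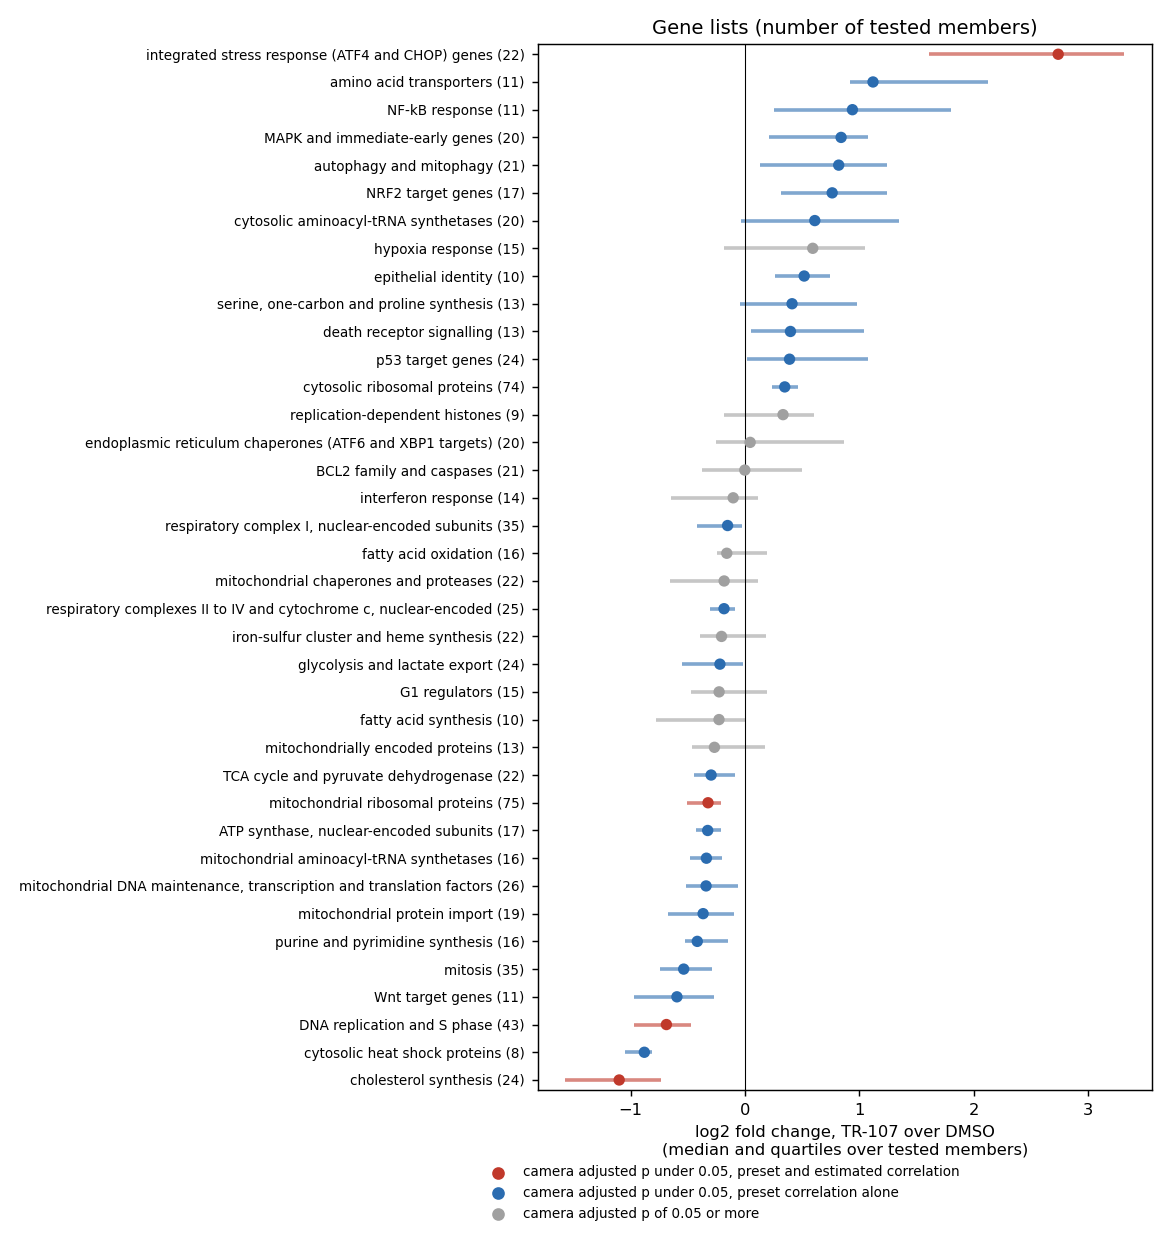
Median (point) and quartiles (line) of log2 fold changes over the tested members of 38 gene lists, TR-107 over DMSO, coloured by camera call. The integrated stress response has the highest median (2.74) and cholesterol synthesis the lowest (-1.10), and 4 lists pass with both the preset and the estimated correlation.

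Mitochondrially encoded genes took 3.70 ± 0.194% of counts in DMSO and 4.87 ± 0.216% in TR-107 (SD, n = 3), higher in 3 of 3 TR-107 libraries than in all DMSO libraries. The exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 allow, as it was for each of 8 such measures, so none can reach 0.05. The 13 protein-coding genes went the other way, from 3.20 ± 0.175% to 2.57 ± 0.142% (SD, n = 3), while the 2 rRNA genes went from 0.483 ± 0.0200% to 2.28 ± 0.0747% (SD, n = 3). These parts were separated after the data were seen. In edgeR's test MT-RNR1 (12S rRNA, 979 to 7412 CPM; adjusted p = 3.75e-05) and MT-RNR2 (16S rRNA, 3743 to 15880 CPM; adjusted p = 2.28e-37) rose. Of the 13 protein-coding genes, 8 fell and 4 rose (9 and 4 adjusted over the list alone). MT-CO2 (-0.91), MT-ND1 (-0.69) and MT-ND4 (-0.52) were among those that fell. MT-CYB (0.79), MT-ATP8 (0.59), MT-ND2 (0.31) and MT-ND3 (0.18) were those that rose. As a list the 13 did not pass camera (adjusted p = 0.139; 0.655 with an estimated correlation). MT-ATP8 overlaps MT-ATP6, and MT-ND4L overlaps MT-ND4, so these genes need not stand for separate mRNAs. MT-ATP6 did not pass (log2 fold change -0.26, edgeR adjusted p = 0.0597), so the rise of MT-ATP8 is uncertain.

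**Figure D4:**
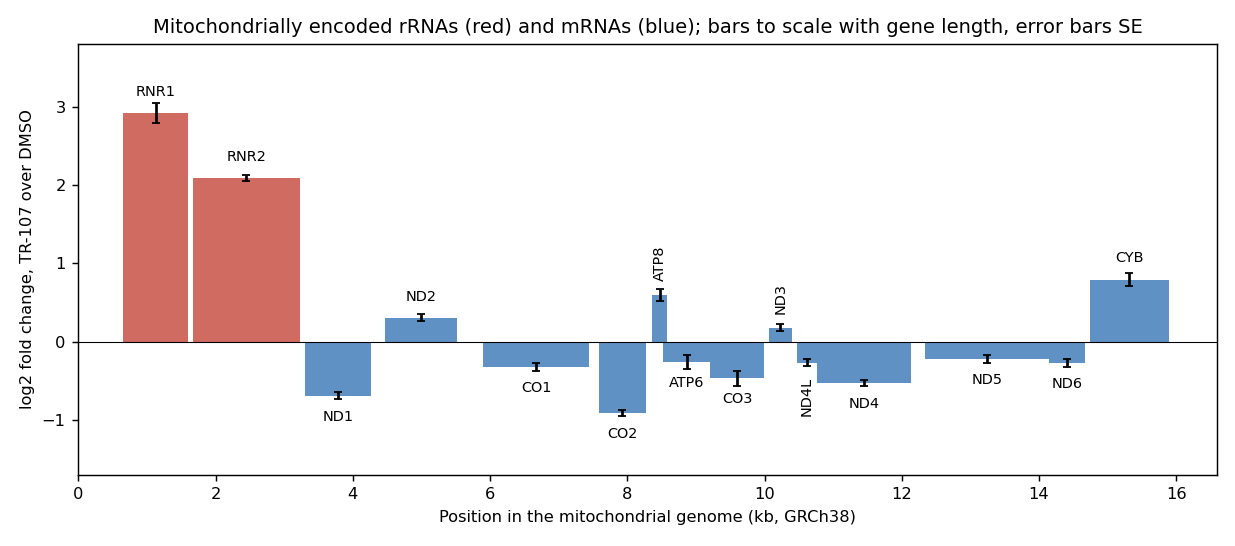
Log2 fold change (TR-107 over DMSO, y axis) of the 2 rRNA genes and 13 protein-coding genes at their GRCh38 positions on the mitochondrial genome (x axis, kb); bar width is gene length and error bars are SE from edgeR's fit, 3 libraries per group. The rRNA genes MT-RNR1 and MT-RNR2 stand at 2.92 and 2.08, and the mRNAs lie between -0.91 (MT-CO2) and 0.79 (MT-CYB); tRNA genes are not drawn.

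Of 43 genes of DNA replication and S phase, 42 fell and 0 rose (43 adjusted over the list alone), with MCM4, a subunit of the replicative helicase, from 619 to 253 CPM, FEN1, a flap endonuclease, from 201 to 82.3 CPM, and PCNA, the sliding clamp, from 224 to 103 CPM. Camera gave an adjusted p of 4.72e-15, and adjusted p = 0.0161 with an estimated correlation. Of 35 mitosis genes, 32 fell and 1, CKS1B (0.41), rose (33 and 1 adjusted over the list alone), with CCNB1, BIRC5 and PLK1 at log2 fold changes of -0.95, -1.01 and -0.85 (camera adjusted p = 8.31e-10, and adjusted p = 0.118 with an estimated correlation). MKI67, a proliferation marker, fell from 717 ± 32.3 to 428 ± 19.7 CPM (SD, n = 3). CCND1 and MYC were 1.32-fold and 1.15-fold lower. The list of 15 G1 regulators, with 5 higher and 8 lower, did not pass camera (adjusted p = 0.379). In it the cyclin-dependent kinase inhibitors CDKN1A (1.76), CDKN2B (1.22) and CDKN1B (0.32) rose and CCND3 (-1.54), CDK6 (-0.49) and CDK2 (-0.45) fell on the log2 scale.

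CDKN1A, the p21 inhibitor, rose from 126 ± 5.28 to 425 ± 3.39 CPM (SD, n = 3), and TNFRSF10B, a death receptor for TRAIL, rose from 123 ± 6.08 to 388 ± 3.43 CPM (SD, n = 3). Both stand in the list of 24 p53 target genes, of which 15 rose and 3 fell, with a median log2 fold change of 0.39. GADD45A (2.05) and BBC3 (1.99) were among those that rose, and PLK2 (-0.53), AEN (-0.32) and TIGAR (-0.25) were those that fell. The list had a camera adjusted p of 0.00252, and adjusted p = 0.118 with an estimated correlation. Of 13 death receptor genes, 8 rose, including TNFRSF1A (1.04) and CFLAR (0.75), and 1, BID (-0.64), fell (camera adjusted p = 0.0102, and adjusted p = 0.0993 with an estimated correlation). TNFSF10, the ligand TRAIL, was too low to test, with 3 counts in DMSO replicate 1 and 0 in the other libraries. Among 21 BCL2 family members and caspases, 8 rose, including PMAIP1 (0.92) and BCL2L2 (1.02), and 7 fell, including BAK1 (-0.38), and the list did not pass camera (adjusted p = 0.558; median -0.0014, mean 0.18, camera direction up).

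Of 24 genes of cholesterol synthesis and uptake, 23 fell and 1 rose, and 14 fell at least 2-fold. The 1 that rose, TM7SF2 (log2 fold change 0.30), lost its call without DMSO replicate 1 or 3 (0.26 both times) or TR-107 replicate 1 (0.31) or 3 (0.28), under DESeq2 (0.30) and with library size alone (0.24). DHCR7, which makes cholesterol, fell from 160 to 53.4 CPM, and INSIG1, a sterol-regulated membrane protein, from 82.1 ± 5.65 to 16.3 ± 1.41 CPM (SD, n = 3). The list had a camera adjusted p of 7.24e-11, and adjusted p = 0.0315 with an estimated correlation. Of 10 fatty acid synthesis genes 4 fell, namely SCD (-1.39), FASN (-0.98), ACLY (-0.84) and FADS2 (-0.38), and 2 rose, ACSS2 (1.01) and ME1 (0.57); the list did not pass camera (adjusted p = 0.205). Of 24 genes of glycolysis and lactate export, 16 fell and 3 rose (16 and 4 adjusted over the list alone), with LDHA, lactate dehydrogenase, from 1163 to 527 CPM, PGAM1 from 577 to 287 CPM, and PDK1, which restrains pyruvate dehydrogenase, up from 9.29 to 19.9 CPM (camera adjusted p = 0.00403, and adjusted p = 0.137 with an estimated correlation). Of 16 purine and pyrimidine synthesis genes, 12 fell, including IMPDH1 (-1.03), CTPS1 (-0.72) and UMPS (-0.71), and 2 rose, GART (0.42) and IMPDH2 (0.26), with a camera adjusted p of 0.00252 and adjusted p = 0.157 with an estimated correlation.

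Of 74 cytosolic ribosomal protein mRNAs 64 rose and 3 fell (65 and 3 adjusted over the list alone), with a median of 1.27-fold. The list had a camera adjusted p of 1.10e-10, and adjusted p = 0.0721 with an estimated correlation. RPL3 went from 1704 to 2821 CPM and RPLP0 from 2266 to 3631 CPM. The 3 that fell were RPS10, RPS26 and RPL17, and RPS10 and RPL17 overlap readthrough genes, so their counts are uncertain. The call of RPL17 was lost without TR-107 replicate 2 (log2 fold change -0.25; edgeR adjusted p = 0.0751, within 0.00148 to 0.0751 over the alternatives). All 8 tested cytosolic heat shock proteins fell, with HSP90AA1 from 5387 to 2710 CPM, HSPA8 from 3341 to 1819 CPM and HSPH1 from 454 to 196 CPM (camera adjusted p = 1e-05, and adjusted p = 0.0993 with an estimated correlation). Of 20 endoplasmic reticulum chaperones, 10 rose and 7 fell (10 and 8 adjusted over the list alone), with the chaperone HSPA5 up from 1117 to 2846 CPM and HERPUD1 up 2.36-fold but CALR down from 1019 to 577 CPM, and the list did not pass camera (adjusted p = 0.453).

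Of 17 NRF2 targets, 12 rose and 3 fell, with the ferritin chains FTH1 (1748 to 6024 CPM) and FTL (1139 to 2610 CPM) and the reductase TXNRD1 (630 to 1493 CPM) higher, and the pentose phosphate enzymes PGD (-0.44), TKT (-0.34) and TALDO1 (-0.19) lower (camera adjusted p = 0.000376, and adjusted p = 0.0771 with an estimated correlation). Of 21 autophagy and mitophagy genes, 14 rose, among them MAP1LC3B (75.4 to 379 CPM) and SQSTM1 (299 to 724 CPM), and 1, BNIP3 (-0.37), fell (camera adjusted p = 4.26e-05, and adjusted p = 0.0721 with an estimated correlation). Of 11 NF-kB response genes 8 rose and 0 fell, including NFKB2 (103 to 172 CPM), and the chemokines CXCL8 and CXCL2 rose from levels under 1 CPM to 3.02 and 3.37 CPM (camera adjusted p = 0.00210, and adjusted p = 0.137 with an estimated correlation). Of 20 MAPK and immediate-early genes, 14 rose and 0 fell, with DUSP5, an ERK phosphatase, from 152 to 739 CPM and EPHA2 from 262 to 640 CPM (camera adjusted p = 2.95e-05, and adjusted p = 0.0913 with an estimated correlation).

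Of 11 Wnt target genes, 9 fell and 0 rose, with AXIN2, a feedback inhibitor of the pathway, from 21.5 ± 1.71 to 4.38 ± 1.10 CPM (SD, n = 3), TCF7 (-0.85) and RNF43 (-0.60) lower on the log2 scale (camera adjusted p = 0.000766, and adjusted p = 0.0993 with an estimated correlation). Of 10 epithelial identity genes, 8 rose and 0 fell, including the splicing factor ESRP1 and the junction genes CLDN7 and CDH1 (log2 fold changes of 0.85 and 0.79 for the last pair), with a camera adjusted p of 0.000485 and adjusted p = 0.0721 with an estimated correlation. Only 3 of 19 intestinal differentiation genes were expressed enough to test: KLF4 rose from 33.0 to 92.1 CPM, CDX2 fell from 24.4 to 17.7 CPM, and CEACAM1 did not pass (0.651 and 1.19 CPM; edgeR adjusted p = 0.168). Of 4 tested metallothioneins, a family of similar copies, 3 rose (4 adjusted over the list alone), MT2A from 511 to 1462 CPM and MT1E from 264 to 568 CPM among them. Of 19 markers of fibroblasts, endothelium and blood, 2 were tested: CD68, also a lysosomal protein of many cells, rose from 5.57 to 11.8 CPM, and COL1A1 did not pass (14.3 and 17.2 CPM; edgeR adjusted p = 0.0660), with 1 and 2 called adjusted over all genes and over the list alone.

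In all, camera called 27 of 38 lists, 12 higher and 15 lower, and with an estimated correlation 4, the integrated stress response (higher), DNA replication, mitochondrial ribosomal proteins and cholesterol synthesis (lower). Fry called 36 lists in 1 direction and 37 as changed in either direction. The call of the serine, one-carbon and proline list was lost without DMSO replicate 1 (camera adjusted p = 0.0767) and without TR-107 replicate 1 (0.0525), 2 (0.0629) or 3 (0.0665), within a range of 0.0265 to 0.0767 over the settings with camera's preset correlation, and fry gave an adjusted p of 5.59e-06. Of the remaining lists that missed camera's threshold, hypoxia response genes had 8 higher and 5 lower of 15 tested (camera adjusted p = 0.0535). NDRG1 (57.7 to 355 CPM) and VEGFA (50.9 to 157 CPM) led those that rose. ADM (34.9 to 22.9 CPM) and BNIP3 (37.8 to 29.2 CPM) were among those that fell. This list passed camera without DMSO replicate 3 (adjusted p = 0.0366), without TR-107 replicate 1 (0.0415) and with library size as the only scaling (0.043), within a range of 0.0366 to 0.0853 over the settings with camera's preset correlation. Camera gave adjusted p = 0.183 with an estimated correlation, and fry 4.28e-05. Iron-sulfur cluster and heme synthesis had 5 higher, led by ALAS1 (73.2 to 182 CPM), and 11 lower, led by CPOX (360 to 120 CPM), of 22 (camera adjusted p = 0.215). Fatty acid oxidation had 5 higher, with ACADVL (159 to 235 CPM), and 7 lower, with CPT1A (158 to 120 CPM), of 16 (camera adjusted p = 0.658). The interferon response had 0 higher and 4 lower, with OAS3 (56.5 to 33.8 CPM), of 14 (camera adjusted p = 0.213). Replication-dependent histones, whose mRNAs lack a poly(A) tail, had 0 called of 9 near the detection limit (camera adjusted p = 0.976).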

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

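The shares of the 13 mitochondrial protein-coding genes and 2 rRNAs alone and the fit without mitochondrial genes were chosen after the data were seen. The number of called genes ran from 7323 to 8021 and the number at least 2-fold apart from 1250 to 1516 over the other scalings, filters and tools and with each library left out. Every gene called both there and in the reported fit kept its direction, 7856 of them with the replicate number as a block, which called 7918 genes, 1407 at least 2-fold apart and 27 lists. Same-numbered libraries did not deviate together (correlations of -0.0311, -0.0185 and 0.0486, with 2 of 6 libraries closest to their own number). No effect shared by number was therefore visible, which does not show that same-numbered cultures were handled separately. A test against 2-fold itself called 545 genes, 385 higher and 160 lower, since it asks for more than a fold estimate above 2. Camera with an estimated correlation called 4 lists, 1 higher and 3 lower. Mitosis (estimated correlation 0.217) and cytosolic heat shock proteins (0.26) lost the call with an estimate above the preset 0.01. Complexes II to IV (-0.0331), complex I (-0.0127) and epithelial identity (-0.0364) lost it with an estimate below 0.01. A larger correlation therefore does not account for every lost call. Losing the call in this form of the test is not by itself evidence that the genes of a list vary together. Library size as the only scaling moved the median of all genes by -0.0643, so that 43.4% of calls were higher in place of 50.5%.

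Of the values of single named genes under the alternatives, 3795 kept direction and side of the threshold, 47 lost the call, 3 gained it and 1 changed sign; of those of lists 519, 27, 16 and 7. The 12 named genes that lost a call were NDUFA13, ATP5MC2, SUCLG2, IDH2, MRPS33, MTIF2, TIGAR, RBL2, EGLN1, TM7SF2, USP18 and RPL17; the histones H1-4 and H2BC17 gained one. CLPX, not called, ran from -0.0991 (without DMSO replicate 2) to 0.0129 (without TR-107 replicate 3) on the log2 scale. Fry gave fatty acid oxidation the direction opposite to camera's, with the same median of -0.16. The histones, not called and near the detection limit, changed camera's direction with medians of 0.27 (library size only), 0.55 (at least 1 CPM in 3 libraries), 0.22 (replicate block), 0.33 (fry), 0.399 (without DMSO replicate 1) and 0.0808 (without DMSO replicate 3). Over all 6 fits with a library left out their median ran from -0.0824 to 0.41. The difference in mitochondrial share, 1.16 percentage points, was 1.10 to 1.29 with a library left out, -0.63 for the 13 protein-coding genes alone and 1.79 for the rRNAs alone; the rRNAs make up the rise. For the other shifts between settings listed here the cause was not tested.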

Other observations

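The added lists of this part, and the tests on RNA without a poly(A) tail and on the ratio of mitochondrial rRNA to mRNA, were chosen after the main results were seen, the 2 tests after their own values too. The length and GC tests and the added lists were set before their own values were computed. The intervals given below for list medians were taken over the genes of a list, as if these varied independently. They hold no error between libraries. Where genes move together they may be too narrow, as for the cytosolic heat shock proteins (estimated correlation 0.26).

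Of 35 tested ribosome biogenesis factors, 33 fell and 1 rose, as many adjusted over the list alone, with a median log2 fold change of -0.37. The list had a camera adjusted p of 1.38e-09, and adjusted p = 0.0705 with an estimated correlation. Nucleolin, NCL, fell from 2079 ± 31.7 to 1258 CPM (SD, n = 3), NOLC1, a nucleolar phosphoprotein, from 769 to 511 CPM, and MRTO4, a ribosome assembly factor, from 199 to 112 CPM, while RRP12 rose from 117 to 154 CPM. Of 31 proteasome subunits, 26 fell and 0 rose (27 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 4.74e-08, and adjusted p = 0.122 with an estimated correlation). PSMD2 fell from 547 to 353 CPM and PSMD3 from 270 to 179 CPM, both regulatory particle subunits.

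The mitochondrial rRNAs rose while most mitochondrial mRNAs did not. The ratio of rRNA to mRNA counts within a library, which no scaling changes, was 0.151 ± 0.00235 in DMSO and 0.886 ± 0.0209 in TR-107 (SD, n = 3), 5.88 times apart, which argues against scaling. Had the TR-107 libraries held more RNA without a poly(A) tail, 13 nuclear genes for such RNA could have risen as well. Of these, 9 are replication-dependent histones, and DNA replication genes fell after TR-107. The histones may therefore fail to rise whatever the amount of such RNA. With that limit, 0 of the 13 rose and 2 fell, RN7SL1 and RN7SL2, with a median of -0.14 (95% interval -0.831 to 0.553). The bound for this interval was raised from 0.3 to 1 after the value was seen; under the bound first written the test would have stayed open, and most of the 13 genes are low. Longer or more frequent poly(A) tails on the rRNA itself, slower decay and more synthesis under TR-107 remain hypotheses that were not tested.

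Of 74 cytosolic ribosomal protein mRNAs 64 rose, while 33 of 35 factors that build ribosomes fell. The ribosomal protein median of 0.342 over 73 genes with a length was 0.305 after a fit on transcript length and GC (95% interval 0.274 to 0.367). Length and GC were those of each gene's longest annotated transcript. The value argues against a bias in these measures as the whole cause. The longest transcript need not be the expressed one, so a bias by the expressed length of these mRNAs stays open. A rise of all mRNAs with a 5' terminal oligopyrimidine tract could also raise them: of 22 others 11 rose, TPT1 and RACK1 among them, and 4 fell, NPM1 among them, with a median of 0.111 (95% interval -0.0182 to 0.346; camera adjusted p = 0.0929), which leaves this open. EEF1A1 (8184 to 17410 CPM), EEF2 (3696 to 6047 CPM) and PABPC1 (3444 to 5181 CPM), further mRNAs of this kind, were kept out of the 22 because their values had been seen, and all 3 rose. Reads shared with ribosomal pseudogenes stay open, as does an effect of the treatment on mRNA stability.

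All 8 tested cytosolic heat shock protein mRNAs fell, while all 22 tested integrated stress response genes rose. After the same fit on length and GC the median of the 8 was -0.91 (95% interval -1.18 to -0.809). The value argues against a bias in these measures as the whole cause, with the same limit on the transcript used. Of 23 further chaperones and co-chaperones, 22 fell and 0 rose, with a median of -0.578 (95% interval -0.708 to -0.489). They were listed as dependent on the transcription factor HSF1, which these data do not show. The list had a camera adjusted p of 1.22e-09, and adjusted p = 0.122 with an estimated correlation. DNAJA1 fell from 369 to 158 CPM and FKBP4 from 515 to 239 CPM. Lower HSF1 activity under TR-107 may account for both lists, a hypothesis that these mRNA levels do not test and that the phosphorylation of HSF1 or its binding to DNA would. Ribosome biogenesis factors and proteasome subunits fell as well (a median of -0.37 for each list). A fall that reaches beyond HSF1-dependent genes is therefore not told apart from it.

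The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 7956 genes, 1413 of them at least 2-fold apart, and 27 lists. The highest of the other splits called 1 gene, 1 at least 2-fold apart and 17 lists, so for each count 1 of the 10 splits, the real one, reached the real value. Each other split holds both treatments on each side in unequal numbers. It thus keeps part of the treatment difference and adds it to the spread within groups, so few called genes follow from the design. Camera with the preset correlation called 17 lists where at most 1 gene was called, so its list calls need not rest on called genes.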
